A study of Mus musculus with 4 samples.

How the data were processed

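RNA from mouse regulatory T cells was sequenced as 4 libraries, and each library came with a table of gene-level counts. The labels name the assay as sequencing of total RNA, while the library protocol they link to is named for polyadenylated RNA. They also link a protocol for the differentiation of CD4+ T cells, whose content was not used here. The labels describe primary cells of the C57BL/6NJ strain, give each library its own biosample and 1 shared donor record, and leave the sex as not collected. They do not say from which animals or cultures the biosamples came, so the p-values below measure only the spread between these biosamples, part of which may be technical.

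The counts are whole numbers of fragments per gene, made by the authors with featureCounts version 1.4.6-p4 on alignments to mm10 with the GENCODE M13 annotation, per the file headers. The same headers record paired fragments with both ends aligned, reverse-stranded counting, exons as the counted feature and the gene as the unit. Under those settings fragments that align to several places were not requested, so genes with near-identical copies can be undercounted. Fragments in exons shared by genes on the same strand can be lost too, whereas antisense genes are kept apart by the strand setting. The aligned files named in the headers carry the words activated and 48h, which is taken here as a note in the headers and not as a group, and the aligner's version is not given in the sources used here. Per the file headers, the deposited length of each gene is the summed length of its exons.

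The design fixed before the data were examined assumed expected counts and TPM among the deposited values. The files hold raw counts instead, so TPM was computed here from the deposited counts and exon lengths, and FPKM likewise for the alternatives. Counts entered the tests as deposited. The files list 50600 genes, of which 50376 received a symbol by matching the Ensembl identifier without its version to the GENCODE M21 names. The 224 genes without a symbol held at most 0.00963% of the counts of a library. Gene types and transcript sequences came from GENCODE M21, and coordinates are those of the deposited tables on mm10. Of the 450 symbols in the 32 gene lists fixed beforehand, 447 were found.

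The libraries held 43821767, 58696937, 73819468 and 52005209 counts for replicates 1 to 4. A gene with 0 counts in a library could still have up to 3 counts at that depth, and the TPM equal to 3 counts in the library where it is highest is given as its floor. Floors cover counting error only, and fragments amplified by PCR are not independent molecules. The intervals of a median given below cover the spread among its genes, not that between libraries. Pairs of libraries were compared by a chi-square test over 14052 genes with at least 40 counts in all. The statistic per degree of freedom lay between 11.1 and 24.4, so no pair agreed within sampling noise. This argues only against a library deposited more than once, since technical repeats of a sample can also differ by more than counting error, and the 4 libraries were treated as replicates because the labels list them as separate biosamples.

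The single group allows no comparison between conditions. Levels were described as the mean ± SD of the 4 libraries, and a gene was called expressed at a TPM of at least 1 in all 4. The regulatory T identity list was compared with the list of each other helper fate as the difference in the mean of log2(TPM + 1) within each library, after members held by both lists were left out. That difference was tested by a two-sided exact sign-flip permutation test over the 4 libraries, whose 16 sign patterns give no p below 0.125. Each replicate was then set against the other 3 with edgeR 4.0.16, using TMM scaling, filterByExpr for 1 group, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. In that test the lone library is assumed to vary like the rest, and it compares libraries, not conditions. With 1 group the filter keeps only genes that reach its count threshold in all 4 libraries. Genes near 0 in any library were therefore not tested. The same tool gave the common biological coefficient of variation, with an intercept only. Benjamini-Hochberg adjustment was also done within each fixed list, and each list's median difference was placed among those of 10000 random lists matched on expression, which ignore the correlation among members of a list.

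The edgeR step was tested on simulated counts for replicate 1 against the other 3, with 12739 genes and 200 of them changed in replicate 1, 50 at each size. It recovered 64% of the genes changed 1.5-fold, 78% at 2-fold, 96% at 4-fold and 80% at 8-fold, where 10 of the 50 genes fell below the expression filter. There were 8 false calls. The simulated genes had the spread of the fitted trend at their mean level, without further differences in spread from gene to gene. The recovered shares may therefore be too high for the real data. The random-list step and a trend with exon length were also tested on simulated shifts.

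Genes are named by a rule written before the data were examined. It takes the 20 genes with the highest mean TPM, the members of the regulatory T identity and effector lists, and from every other list its first gene and its 3 most abundant members. It adds the called genes of each replicate with the largest differences, called members of the fixed lists, the 10 genes with the largest dispersion at a mean of at least 10 CPM (counts scaled to a common library total), all sex-linked genes and the 10 most counted T cell receptor beta variable genes. Some genes that the rule takes are not reported here. Genes outside it that are named below were chosen after their values were seen. The alternatives were another TPM threshold, unit, pseudocount or list summary, another normalization or filter, DESeq2 1.42.0, and leaving out each replicate in turn. Alternatives that needed posterior mean values could not be run on counts. Thinning every library to the smallest total, a robust fit and a histone share without H1f0 were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.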

Results

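Regulatory T cells, the CD4+ lymphocytes that restrain immune responses and depend on the transcription factor Foxp3, were profiled in 4 replicate biosamples of the C57BL/6NJ mouse strain. All 4 libraries belong to 1 group, and no other cell type or treatment is set against them. The total was 43821767 counts in replicate 1, 58696937 in replicate 2, 73819468 in replicate 3 and 52005209 in replicate 4. Values below are the mean ± SD of the 4 libraries (n = 4) in TPM, counts divided by exon length and scaled to the sum of these values in the library, unless stated.

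The cells transcribed 11593 genes at a TPM of at least 1 in all 4 libraries, 10274 of them protein coding, and 2015 genes exceeded a TPM of 100 in all 4. The most abundant transcripts served protein synthesis, the cytoskeleton and energy metabolism. Actb, a cytoskeletal actin, stood at 10054 ± 432 TPM, and the elongation factors Eef1a1 and Eef2 at 9956 ± 521 and 7436 ± 448. The ribosomal proteins Rplp1, Rpl8, Rplp0, Rps2, Rpl4 and Rps15 lay between 3746 and 9349 on average, beside the chaperone Hsp90ab1 at 6584 ± 284, the translation factor Eif5a at 2736 ± 76.3 and the actin-binding Tmsb4x at 2942 ± 281. Mitochondrial mt-Co1, mt-Nd1 and mt-Cytb reached 6125 ± 401, 3720 ± 281 and 3105 ± 48.5. Lactate dehydrogenase Ldha at 3679 ± 159 and the cytokine lymphotoxin alpha, Lta, at 2702 ± 98.9 were also among the 20 most abundant genes. The remaining 3 were Gm23935 at 14548 ± 2213, Gm42418 at 4185 ± 995 and Gm24187 at 3028 ± 906. Gm23935 and Gm24187 are 57 bases long and identical at 56 of them, so their counts and their division between the 2 genes are uncertain. Their TPM also rests on division by that short length. Gm23935 had 10135 to 18030 counts per library, while Actb had 362112 to 572090 over 2679 bases. All mitochondrial genes made up 1.83 ± 0.11% of TPM.

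Many genes of the regulatory T identity list were abundant in every library, and others were low. No other T cells were set against these, so the levels do not tell which members are particular to regulatory T cells. Of the 22 genes of the regulatory T identity list, 21 reached a TPM of 1 in all 4 libraries and 11 exceeded 100. Foxp3, the lineage-defining factor (ENSMUSG00000039521.12, chromosome X, 7579676 to 7595243 of mm10), stood at 289 ± 23.5 TPM, with 6.69% of its exon bases shared with another gene on the same strand. The interleukin 2 receptor chain Il2ra was the most abundant member at 1488 ± 19.4, followed by the tumour necrosis factor receptor family members Tnfrsf4 at 1190.1 ± 15.4 and Tnfrsf18 at 580.2 ± 18.2. The inhibitory receptor Ctla4 reached 444 ± 27.4, the actin-capping protein Capg 552 ± 12.1, the folate receptor family member Izumo1r 284 ± 20.8 and Tnfrsf9 278 ± 11.2. Rgs16, Tnfrsf1b, Cd83 and the Ikaros family factor Ikzf4 lay at 242 ± 14.5, 204 ± 11.6, 166 ± 7.54 and 104 ± 7.09.

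**Figure D1:**
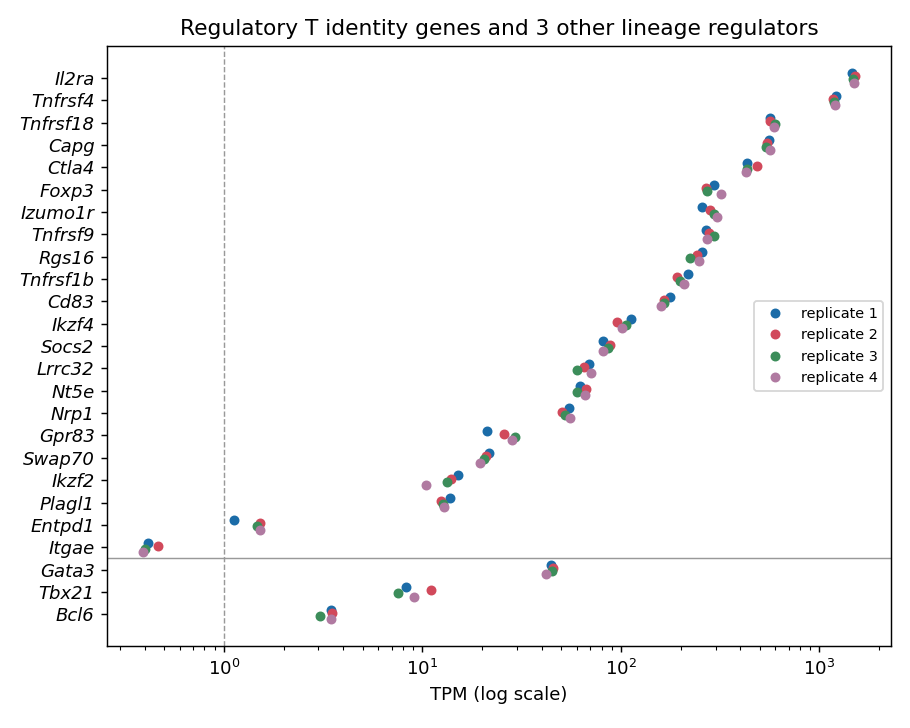
TPM of the 22 regulatory T identity genes, ordered by their mean, and of the lineage regulators Gata3, Tbx21 and Bcl6, on a log axis, with a point for each of the 4 replicates and a dashed line at a TPM of 1. Il2ra lies near 1488 and Foxp3 near 289, while Itgae, at 0.419, is the member to the left of the line.

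Further identity genes were lower. Socs2, Lrrc32, Nt5e and Nrp1 ranged from 53.3 to 84.1 TPM on average, and Gpr83, Swap70, Ikzf2 and Plagl1 from 13.0 to 26.1, with Ikzf2, which encodes Helios, at 13.2 ± 1.99. The ectonucleotidase Entpd1, which encodes CD39, was near the threshold at 1.41 ± 0.194, whereas Nt5e, which encodes CD73, stood at 63.9 ± 3.36. The integrin chain Itgae stayed below a TPM of 1 in every library, at 0.419 ± 0.0341. The count of 21 became 20 with a TPM threshold of 5 or an FPKM threshold of 1.

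Effector genes of regulatory T cells were split between abundant and scarce transcripts. Of 17 members, 10 were expressed in all 4 libraries. The chemokine receptor Ccr8 stood at 468 ± 10.6, the checkpoint receptor Pdcd1 at 315 ± 16.1, Tgfb1, which encodes transforming growth factor beta 1, at 302 ± 7.0, and Ebi3, a chain of interleukin 35, at 168 ± 12. Icos at 85.0 ± 4.53, Lag3 at 61.4 ± 4.34 and Tigit at 21.3 ± 3.02 were lower, and Il1r2 and Fgl2 were close to the threshold at 1.57 ± 0.221 and 1.24 ± 0.159. The opioid precursor Penk differed between libraries, with 44.4, 34.2, 19.2 and 24.8 TPM in replicates 1 to 4. Il10, Gzmb, Prdm1, Areg, Il1rl1 and Havcr2 averaged below 0.8 TPM. Klrg1 had 0 counts in all 4 libraries, against a floor of 0.168 TPM.

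Markers of the other helper T cell fates were lower as lists, although each list held abundant members. The identity list exceeded the type 1 helper list by 3.23 ± 0.08 on the log2 scale, the type 2 list by 3.81 ± 0.06, the type 17 list by 3.36 ± 0.09 and the follicular list by 3.56 ± 0.01. Each difference was above 0 in 4 of 4 libraries, with p = 0.125 in the exact sign-flip permutation test, the smallest that 4 libraries allow. Among the lineage regulators, Foxp3 was 32.8 ± 5.61 times as abundant as Tbx21, 6.56 ± 0.79 times Gata3 and 85.6 ± 6.96 times Bcl6. Both kinds of comparison set different transcripts side by side within a library and do not compare these cells with other helper cells. Restricting the lists to members with a TPM of 1 in some library lowered the type 17 difference to 1.92.

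Of 15 type 1 helper genes, 11 were expressed. Tnf at 277 ± 2.63, Ccl4 at 220.2 ± 24.6 and Il12rb1 at 85.3 ± 7.83 led the list, while Tbx21, the type 1 regulator, stood at 8.99 ± 1.52 and the cytokine gene Ifng at 0.747 ± 0.667. Of 14 type 2 genes, 7 were expressed, led by the chemokine receptor Ccr4 at 342 ± 23.2, Il4ra at 115 ± 7.84 and Igfbp7 at 59.4 ± 4.75. Gata3, the type 2 regulator, was at 44.2 ± 1.67. Of 14 type 17 genes, 9 were expressed, led by Ccr6 at 371 ± 27.3, Batf at 144 ± 9.08 and Ahr at 63.5 ± 8.60. Of the 12 follicular genes, 8 were expressed, with Id3 at 111 ± 8.66, Cd200 at 76.1 ± 8.51, Btla at 70.3 ± 2.79 and the follicular regulator Bcl6 at 3.38 ± 0.219. Named outside the rule, after their values were seen, the cytokine genes Il17f and Il17a stood at 46.6 ± 8.03 and 6.60 ± 1.31, Il4 at 0.286 ± 0.339, and Il22 and Il21 had 0 counts in all libraries.

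Transcripts of the T cell lineage were abundant and those of most other blood and tissue cells were scarce. All 18 members of the pan T list were expressed, led by the receptor constant gene Trac at 1053 ± 43.9, Thy1 at 919 ± 17.9 and the kinase Lck at 785 ± 14.3, with Cd3e at 171 ± 10.3. Of 16 naive T cell genes, 15 were expressed. Tcf7 stood at 599.7 ± 11.1, Ccr7 at 355 ± 7.20 and Actn1 at 163 ± 7.93. Of 12 genes of CD8 and natural killer cells, 2 were expressed, Nkg7 at 72.1 ± 9.56 and Cd8b1 at 11.7 ± 1.75, while Cd8a was at 0.187 ± 0.0869 and Eomes at 1.20 ± 0.351. Of 8 thymocyte genes, Themis was expressed at 18.2 ± 0.941, while Dntt was at 0.717 ± 0.417, Cd8a at 0.187 ± 0.0869 and Rag1 at 0.0645 ± 0.0797. None of the 7 genes of gamma delta and innate-like T cells found in the files was expressed, with Trdc at 0.871 ± 0.224, Tcrg-C2 at 0.285 ± 0.136 and Tcrg-C1 at 0.127 ± 0.146.

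Of 12 B cell genes, 4 were expressed. Ighm, the constant gene of the mu heavy chain, stood at 403 ± 14.5, Ighd at 8.67 ± 2.15 and Igkc at 4.89 ± 1.49. Of the 16 genes of macrophages and dendritic cells, 3 were expressed, namely Cd74 at 286 ± 23.7, Cd68 at 4.23 ± 0.990 and Adgre1 at 1.30 ± 0.328, and Lyz2 had 0 counts against a floor of 0.180 TPM. No gene of granulocytes and mast cells was expressed. Siglecf reached 0.313 ± 0.136, Cma1 0.0430 ± 0.0860 and Ngp 0.0136 ± 0.0272, and S100a8 had 0 counts in all libraries, against a floor of 0.342 TPM. No erythroid or platelet gene was expressed either, with Itga2b at 0.618 ± 0.268, Klf1 at 0.411 ± 0.372, Hbb-bt at 0.218 ± 0.253 and 0 counts for Hba-a1, for which fragments shared with a near-identical copy would not have been counted. Of the 12 stromal and epithelial genes, Pecam1 was expressed at 7.99 ± 1.10, with Epcam at 0.727 ± 0.310, Krt18 at 0.575 ± 0.299 and Col1a1 at 0.120 ± 0.0892.

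Many T cell receptor beta variable genes were used in every library. Between 23 and 24 of the 35 had a count, and no single gene held more than 11.4% of the variable gene counts of a library. The totals behind these shares were 3766, 5615, 6873 and 4853 counts in replicates 1 to 4. Trbv19 held 10.3 ± 0.58%, Trbv1 10.04 ± 0.42%, Trbv13-2 9.75 ± 1.27%, Trbv31 9.48 ± 0.87% and Trbv3 8.59 ± 0.99%. Trbv2, Trbv16, Trbv13-1, Trbv15 and Trbv13-3 followed with 5.06% to 7.92% on average. These are shares of counts not divided by exon length, and the order differs in TPM. Among these genes Trbv13-2 was the highest there at 90.3 ± 9.04, while Trbv19 stood at 57.6 ± 1.25. Members of the Trbv13 family are related in sequence, so fragments that fit several of them may be missing.

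Genes of cell division and T cell receptor signalling were abundant. All 20 S phase genes were expressed, led by Rrm2, a ribonucleotide reductase subunit, at 597 ± 9.43, Mcm3 at 519 ± 32.0 and the sliding clamp Pcna at 508 ± 21.6. All 20 genes of G2 and M phase were expressed too, led by Cdc20 at 508 ± 22.9, Top2a at 386 ± 4.34 and Plk1 at 317 ± 20.7, with the proliferation marker Mki67 at 292 ± 16.7. The 15 early response genes of the receptor were all expressed, with Irf4 at 773 ± 26.0, Nr4a1 at 738 ± 69.0 and Myc at 543 ± 23.5. All 15 members of the interleukin 2 and STAT5 list were expressed, with Lta at 2702 ± 98.9, Il2ra at 1488 ± 19.4, Il2rb at 909 ± 29.8 and the feedback inhibitor Cish at 365 ± 12.3.

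**Figure D2:**
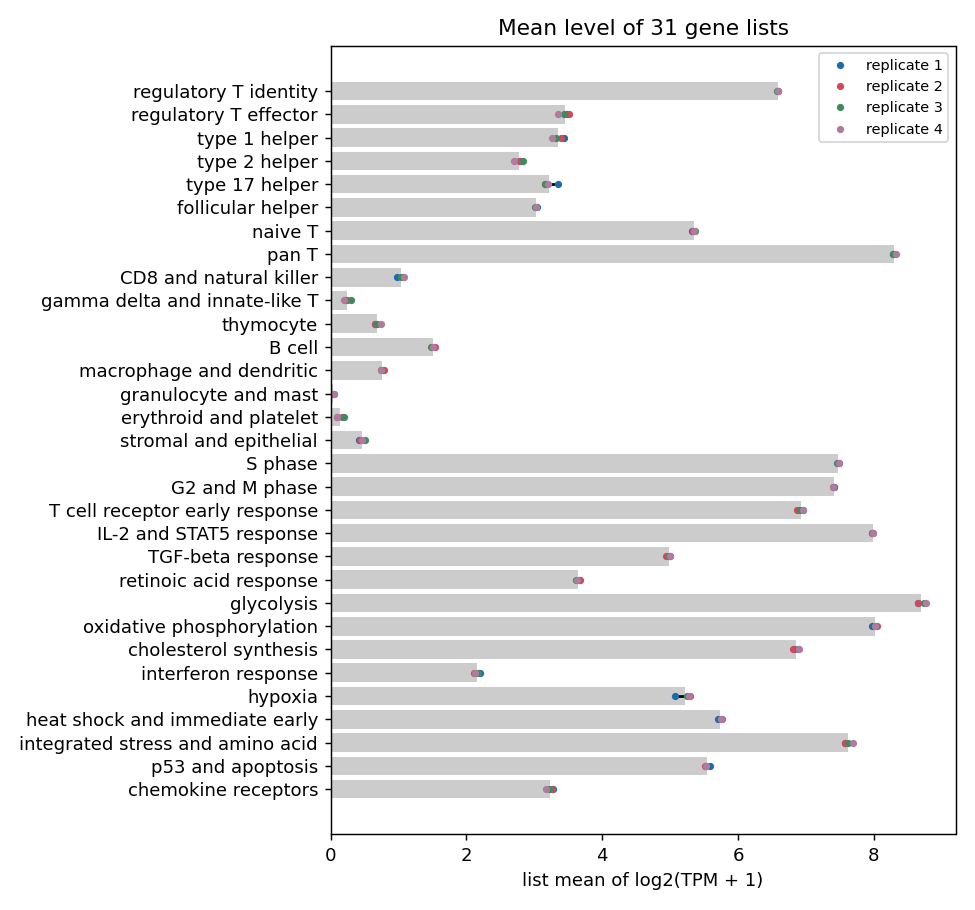
Mean of log2(TPM + 1) over the members of 31 gene lists, with grey bars for the mean of the 4 libraries, black lines for the SD and points for each replicate. The regulatory T identity list stood at 6.58 and the pan T list at 8.29, against 0.04 for granulocytes and mast cells.

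Of the 15 genes of the transforming growth factor beta response, 12 were expressed, led by Bhlhe40 at 356 ± 18.0, Tgfb1 at 302 ± 7.0 and Ski at 154 ± 6.92, with the inhibitor Smad7 at 27.8 ± 1.19. Of 12 genes of the retinoic acid response, 8 were expressed, led by the retinol transporter Stra6 at 315 ± 27.3, the integrin chain Itgb7 at 131 ± 8.56 and the receptor Rxra at 126 ± 22.3, whereas the gut-homing receptor Ccr9 averaged 0.00647 ± 0.0129. Among 16 chemokine and trafficking receptors, 9 were expressed. Ccr8 at 468 ± 10.6, Ccr6 at 371 ± 27.3 and Ccr7 at 355 ± 7.20 led, and Ccr1 had 0 counts against a floor of 0.0838 TPM.

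Every member of the 3 metabolic lists was expressed. All 16 glycolysis genes were expressed, led by Ldha at 3679 ± 159, Pkm at 1912 ± 97.7 and Gapdh at 1820.4 ± 79.0, with the glucose transporter Slc2a1 at 196 ± 6.18. All 17 genes of oxidative phosphorylation were expressed, led by Atp5b at 1758 ± 25, Atp5a1 at 1577 ± 30.6 and Cyc1 at 735 ± 20.4, with Ndufa4 at 254 ± 19.5. All 17 genes of cholesterol synthesis were expressed, led by their regulator Srebf2 at 511 ± 34.7, Hmgcs1 at 375 ± 10.5 and Cyp51 at 358 ± 11.4.

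Stress lists differed in level. In the integrated stress and amino acid list, 15 of 16 genes were expressed, led by the factor Atf4 at 1090.0 ± 38.6, the amino acid transporter chain Slc7a5 at 920.2 ± 27.7 and Shmt2 at 873 ± 68.5, with Ddit3 at 27.9 ± 1.80. Of 16 heat shock and immediate early genes, 13 were expressed, with Hspd1 at 1251 ± 33.9, Junb at 1141 ± 75.3 and Hsp90aa1 at 825 ± 31.1, while Hspa1a was at 0.325 ± 0.224. Of 12 p53 and apoptosis genes, 11 were expressed, led by Cdkn1a at 381 ± 13.5, Ccng1 at 353 ± 16.7 and Bax at 334 ± 15.3. All 14 hypoxia genes were expressed, with Egln3 at 156 ± 11, Ero1l at 103 ± 5.92, P4ha1 at 91.0 ± 5.77 and Bnip3 at 41.6 ± 9.72. Of 20 interferon response genes, 8 were expressed, led by Bst2 at 224 ± 11.4, Igtp at 135 ± 16.0 and Ifi47 at 135 ± 12.5, while Isg15 stood at 3.61 ± 1.30.

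Transcripts without a polyA tail bear on which RNA was sequenced, since the assay label and the named library protocol differ. Histone genes held 0.0309 ± 0.0047% of TPM. The share was 0.0189% without H1f0, a replication-independent histone at 121 ± 18.9 TPM chosen after its value was seen, and 0.0113% of counts. Other transcripts without a tail, likewise chosen after their values were seen, were the RNA of the 7SK particle, Rn7sk, at 13.1 ± 3.06 TPM, Rpph1 at 21.1 ± 5.24 and Rmrp at 5.26 ± 2.85. Of the further RNAs looked at beside them, the mitochondrial ribosomal mt-Rnr1 and mt-Rnr2 were far higher, at 593 ± 89.7 and 570 ± 76.3. Malat1 stood at 24.1 ± 3.69, Neat1 at 7.54 ± 0.380 and Terc at 1.27 ± 0.682. These values do not settle which RNA was sequenced. Protein-coding genes held 95.1 ± 0.40% of TPM. Many histone genes are near-identical copies, so their share is a lower limit.

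The replicates differed little from each other across the transcriptome. The common biological coefficient of variation was 0.085, and the median gene among those expressed had a coefficient of variation of 6.52%. Across 11593 expressed genes, Pearson's r of log2(TPM + 1) between pairs of libraries lay between 0.992 and 0.995, and genes are not independent replicates. Among the genes that passed the expression filter with at least 10 CPM, the 10 with the largest dispersion were Xist, Arhgap18, H2-Q7, Ppip5k2, Il27ra, Penk, Gm26917, Gm43305, Scand1 and Cebpb. The class I gene H2-Q7 had 20.2, 22.8, 7.90 and 10.4 CPM in replicates 1 to 4, and the cytokine receptor Il27ra had 65.2, 60.6, 31.4 and 31.3. Without the expression filter the common coefficient was 0.102.

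Sex-linked genes lay at opposite levels in the libraries, and 0 of the 6 on the list were expressed in all 4. Xist, the RNA that silences an X chromosome, was at 172 and 145 TPM in replicates 1 and 2 and at 0.255 and 0.367 in replicates 3 and 4. The Y-linked gene Ddx3y was at 0.152, 0.0781, 45.1 and 45.0 TPM in replicates 1 to 4, and Eif2s3y at 0.0761, 0.0836, 48.3 and 57.7. Uty was at 0.0323, 0.0355, 8.31 and 8.73, Kdm5d at 0.0365, 0.0344, 10.043 and 10.037, and Tsix was below 0.08 in every library. These are values of single libraries, and no groups were formed from them.

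**Figure D3:**
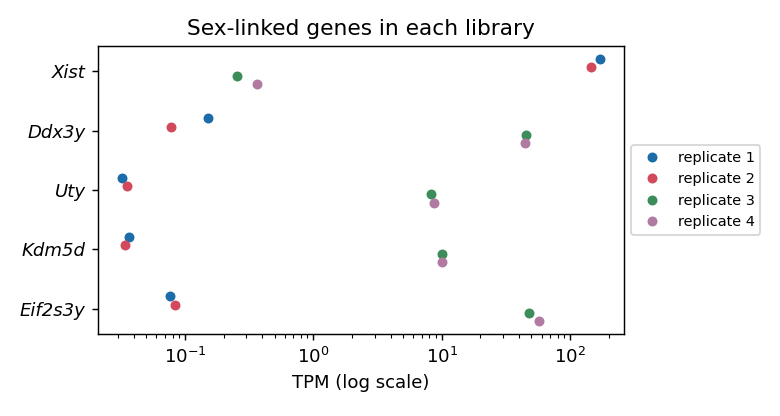
TPM of the sex-linked genes with a count in every library, on a log axis, with a point for each of the 4 replicates. Xist lies at 172 and 145 in replicates 1 and 2 and below 0.4 in replicates 3 and 4, and the 4 Y-linked genes lie the other way round.

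Replicate 1 differed from the other 3 in 9 of 12917 genes, 6 higher and 3 lower, at a Benjamini-Hochberg adjusted p below 0.05 in edgeR's quasi-likelihood test, and in each of the 9 it lay outside the range of the other 3 libraries. The 4 largest increases were in Gm26917, a long non-coding RNA next to Gm42418 on chromosome 17, by 0.95 (SE 0.07) on the log2 scale, Gm24187 by 0.74 (SE 0.10), Gm42418 by 0.59 (SE 0.06) and Lars2, a mitochondrial leucyl-tRNA synthetase, by 0.55 (SE 0.08), with Benjamini-Hochberg adjusted p from 9.7e-09 to 0.0018 in edgeR. The retinoid receptor Rxra, by 0.42 (SE 0.08), and the ribosome biogenesis factor Rrp9, by 0.35 (SE 0.07), were also higher, with adjusted p of 0.045 and 0.031 in edgeR. Bnip3, a mitophagy receptor induced by hypoxia, fell by 0.75 (SE 0.12), the mitochondrial ribosomal RNA mt-Rnr1 by 0.46 (SE 0.07) and Eef1a1 by 0.16 (SE 0.03), with adjusted p from 0.0018 to 0.031 in edgeR. Gm26917 had 1164 CPM against a mean of 601 in the others, and Bnip3 18.2 against 30.6. The counts of Gm24187 are uncertain for the reason given above.

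**Figure D4:**
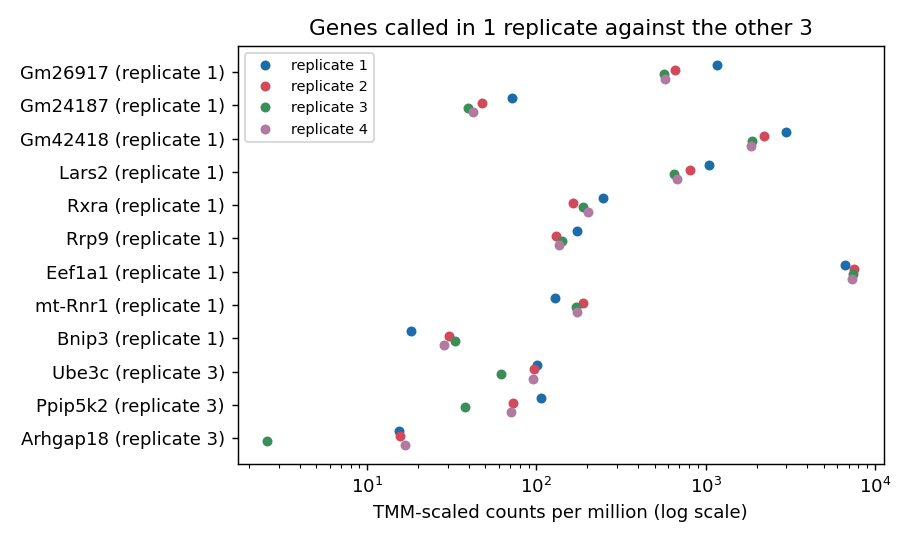
TMM-scaled CPM, on a log axis, of the 12 genes called in a replicate against the other 3, with the replicate in brackets and a point for each of the 4 libraries. Arhgap18 lies at 2.55 in replicate 3 and near 16 in the rest, and Gm26917 at 1164 in replicate 1 and near 600 in the rest.

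Of the members of the fixed lists, Rxra and Bnip3 were called in replicate 1 over all genes tested, and 24 members in 11 lists were called when adjusted over the list alone. In the hypoxia list 1 of 14 members was called over all genes and 6 adjusted over the list alone, all 6 lower in replicate 1. They were Bnip3, Vegfa, Ak4, Higd1a, Pdk1 and Egln3. The list's median difference was -0.17, at percentile 0.0 of 10000 random lists. In the type 17 list Il17f and Ahr were called adjusted over the list alone, with estimates 0.44 and 0.32 higher in replicate 1, as were Ldha, Pgk1 and Slc16a3 in the glycolysis list, with estimates of -0.13, -0.27 and -0.33. DESeq2 called 18 genes, without Lars2 and Eef1a1, a fit without the expression filter 105, without Eef1a1, and libraries thinned to equal depth 35, while Gm42418, Lars2 and Eef1a1 lost their calls in a robust fit and Rrp9 at a mean of at least 5 CPM. Leaving out replicate 2, 3 or 4 gave 112, 23 or 341 genes, and Eef1a1 lost its call without replicate 2 or 3.

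Replicate 3 differed from the other 3 in 3 of 12917 genes, all 3 lower than in each of the other libraries. Arhgap18, which encodes a GTPase-activating protein (chromosome 10, 26753421 to 26918648), fell by 2.64 (SE 0.19) on the log2 scale, from 15.9 CPM in the others to 2.55, with a Benjamini-Hochberg adjusted p of 1.1e-06 in edgeR. The inositol phosphate kinase Ppip5k2 (chromosome 1, 97706048 to 97770411) fell by 1.14 (SE 0.17) with an adjusted p of 0.020, and the ubiquitin ligase Ube3c (chromosome 5, 29569242 to 29676092) by 0.66 (SE 0.09) with an adjusted p of 0.0068 in edgeR. Ppip5k2 also varied among the other libraries, at 107, 72.6 and 70.6 CPM in replicates 1, 2 and 4. No member of a fixed list was called over all genes, and 5 were adjusted over the list alone, among them Penk, Socs1 and Usp18, with estimates of -0.83, 0.40 and -1.93, and Xist, the 1 tested member of its list. DESeq2 called 8 genes and a fit without the expression filter 35, and Ppip5k2 lost its call in DESeq2, in a robust fit and at a mean of at least 5 CPM. Leaving out replicate 1, 2 or 4 gave 16, 17 or 21 genes, with all 3 still called.

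In replicates 2 and 4 no gene that passed the expression filter was called against the other 3 in edgeR. Genes near 0 in a library, such as the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d, were not among those tested. At an unadjusted p below 0.05 in edgeR, 876 of 12917 genes passed in replicate 2 and 322 in replicate 4, against 1202 in replicate 1 and 299 in replicate 3. DESeq2 called 28 genes in replicate 2 and 0 in replicate 4. No member of a fixed list was called over all genes. Adjusted over the list alone, Igtp and Itga2b were called in replicate 2, with estimates of 0.29 and -1.29. Itga2b, at 0.618 ± 0.268 TPM, was the 1 tested member of its list, so its p was in effect not adjusted. In replicate 4 the genes called over the list alone were Ikzf2, Sh2d1a and Dntt, with estimates of -0.44, -0.32 and 1.39, and Xist. Dntt was 1 of 2 tested members of its list, and Xist was the 1 tested member of its own. Without the expression filter edgeR called 60 and 16 genes. Leaving out replicate 1, 3 or 4 gave 52, 3 or 9 genes for replicate 2, and leaving out replicate 1, 2 or 3 gave 2, 2 or 9 genes for replicate 4.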

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

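Each value was compared over the 4 libraries with a test for a single library far from the rest, which chance meets in about 1 of 20 values. Of 234 values, 17 met it. Among them, Gm26917, Ube3c and Arhgap18 had been named because a library stood apart in them, so for these the test restates the selection and the chance rate does not hold. The tests of library size, of transcripts without a polyA tail and of sex mixture were chosen after the results were seen.

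Replicate 1 was set apart by 5 values. Actb was highest there at 10702 TPM against at most 9864 in the rest, Ccr6 at 411 against 363 and Gm26917 at 1204 against 676. The gene with the most counts held 0.826% of all counts there, against at most 0.775% in the rest. That gene was Actb in replicates 1, 2 and 3 and Eef2 in replicate 4, so this value largely restates that of Actb. Entpd1 was lowest in replicate 1 at 1.12 TPM against at least 1.47. In replicate 2, Ctla4 was highest at 484 against 434, Ccr8 at 484 against 464 and Tsix at 0.0764 against 0.0076, and Myc was lowest at 508 against 553. In replicate 3, Bcl6 was lowest at 3.05 against 3.46, Ube3c at 22.2 against 34.3 and Arhgap18 at 1.32 against 8.04. Cma1 was highest there at 0.172 against 0, as was the number of genes at a TPM of 1, 12581 against 12457. In replicate 4, Dntt was highest at 1.34 against 0.543, Ngp at 0.0543 against 0 and Ccr9 at 0.0259 against 0. The values of Cma1, Ngp and Ccr9 rest on 4, 1 and 4 counts.

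The genes called higher in replicate 1 were led by Gm26917, Gm24187 and Gm42418. Every called gene stayed called after every library was thinned to the smallest total, so the calls did not need the greater depth of the others. Replicate 1 is itself the smallest library and was not changed by thinning. The test therefore cannot decide on other effects of its size. Less complete selection of polyadenylated RNA needs a rise in transcripts without a tail. In replicate 1, 40 such transcripts had a median log2 difference of -0.26 (95% order-statistic interval -0.64 to -0.11). Histone genes among them can be short, such as Hist1h3c with 489 bases against a median of 3859 for the genes tested. The shortest genes tested were also lower in replicate 1, with a median difference of -0.07. The interval covers genes of 1 library, not the spread between libraries. The fall therefore cannot decide on less complete selection. Ribosomal RNA fragments that align to these loci remain a candidate explanation. Of the 5 other genes called higher, 0 shared 31 bases with the 1831-base Gm42418 transcript, which met the bound set beforehand against this explanation, but that bound was wrong, since Gm26917 lies 616 bases from Gm42418 on the same strand and shares no sequence with its transcript, which thus holds only part of the locus. That judgement was made after the 0 was seen, and no biological explanation was tested.

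The genes called lower in replicate 3 were Arhgap18, Ppip5k2 and Ube3c, on 3 chromosomes. A loss of DNA that reaches neighbouring genes is argued against, since the 20 tested genes within 1 Mb had a median log2 difference of 0.094 (95% order-statistic interval -0.02 to 0.14). These pool 11 neighbours of Ube3c, from -0.20 to 0.35, 7 of Ppip5k2, from 0.006 to 0.32, and only 2 of Arhgap18, at -0.03 and 0.07. For Arhgap18 the argument thus rests on 2 genes. The calls did not need the greater depth of replicate 3, since every called gene stayed called after thinning. Thinning keeps the expected share of each gene in a library, so it cannot decide on other effects of library size. A variant within each gene, carried by that biosample, may still account for the lower counts and was not tested, nor was any biological explanation.

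Xist and the Y-linked genes lay at opposite levels in each library. Cells of both sexes mixed in a library are argued against, since in no library did the lower of the 2 signals exceed 0.245% of its highest level. Replicates 1 and 2 carried the transcripts of female cells and replicates 3 and 4 those of male cells. Animals of both sexes thus contributed, despite the shared donor record. Il27ra and H2-Q7 were also higher in replicates 1 and 2, and the glycolysis medians given below changed sign between the same pairs. Such splits cannot be told apart from sex here. The sex of the animals is not a group in the labels, and no biological explanation for these splits was tested.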

How the results depend on the processing

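The thinned libraries, the robust fit and the histone share without H1f0 were chosen after seeing the data. The numbers of expressed genes and of regulatory T identity genes expressed stayed within 1.5 times under every alternative run, at 9451 to 12543 and 20 to 21. The 4 list differences stayed above 0 in all alternatives run, at 1.92 to 5.40, and with 4 libraries no p could pass 0.05. Alternatives on posterior mean values could not be run, because the files hold counts. The histone share was 0.0113% of counts and 0.0189% without H1f0, whose construction shows the cause, and 0.0288% to 0.0325% with a replicate left out. The common coefficient of variation was 0.102 without the expression filter, and 0.082 to 0.090 with a replicate left out.

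The counts of genes called in a replicate against the other 3 depended most on the settings, and the cause was not tested. Leaving out the replicate of the same sex set the lone library against libraries of the other sex only. Calls in that setting cannot be told apart from sex. Xist, Kdm6a and Eif2s3x were among them for replicates 2, 3 and 4. Without the filter the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d entered the test and were called for replicates 2, 3 and 4. DESeq2 called 18, 28 and 8 genes for replicates 1, 2 and 3, against 9, 0 and 3 in edgeR. Without a filter beyond a count above 0, edgeR called 105, 60, 35 and 16 genes for replicates 1 to 4. Thinned to the smallest library, replicate 1 had 35 calls, and the robust fit gave 1 for replicate 2. With another replicate left out the counts ran from 23 to 341 for replicate 1, 3 to 52 for replicate 2, 16 to 21 for replicate 3 and 2 to 9 for replicate 4. Lars2 and Eef1a1 lost their calls in DESeq2 and in the robust fit, Gm42418 in the robust fit, Rrp9 with a mean of at least 5 CPM, Ppip5k2 in these 3 settings, and Eef1a1 also without a filter and without replicate 2 or 3. With DESeq2's size factors in edgeR the counts were 9, 0, 3 and 0. Thinning lowered the count of no replicate. In the simulation 64% of 1.5-fold changes were recovered for replicate 1, a share that may be too high for the real data.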

Other observations

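Some gene lists had a median difference near the edge of random lists in a library, although 0 of their members were called there over all genes. The random lists ignore the correlation among members of a list. Counting both tails of the outer 5% of random lists, 3, 4, 2 and 5 of all 31 lists lay in the upper tail in replicates 1 to 4. In the lower tail lay 5, 2, 4 and 1. A percentile near an edge thus does not by itself mark a list out. The glycolysis list had median log2 differences of -0.07, -0.10, 0.07 and 0.09 in replicates 1 to 4, each against the other 3 libraries, at percentiles 0.17, 0.3 and 99.99 of 10000 random lists of matched expression in replicates 1 to 3 and above every such list in replicate 4, and 3, 0, 0 and 0 members were called adjusted over the list alone. The integrated stress and amino acid list had a median of 0.11 in replicate 4, above every random list, with 0 members called adjusted over the list alone. In replicate 2 the retinoic acid list had a median of 0.13, at percentile 99.6, again with 0 such members. The type 17 list had medians of 0.20 in replicate 1 and -0.11 in replicate 3, at percentiles 99.9 and 0.74, with 2 and 1 such members. These were picked from 31 lists in each of 4 libraries after their values were seen, and they are not tests across replicates.

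Some transcripts known mainly from other cells were far more abundant than others of the same lists. Ighm stood at 403 TPM, while Ighd was at 8.67, Igkc at 4.89, Cd79b at 3.11, Cd79a at 0.395 and Ms4a1 at 0.0151, and Cd74 stood at 286 TPM while H2-Aa was at 0.0759. Cd8b1 reached 11.7 TPM with Cd8a at 0.187.

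The genes that DESeq2 called in replicate 2, where edgeR called 0 and 876 passed an unadjusted p below 0.05 in edgeR, were long. Of the 28, 27 were lower in replicate 2 and 27 exceeded the median exon length of the genes tested, with a median of 13357 bases against 3859. Over 12917 genes, Spearman's rho between exon length and the log2 difference was 0.171, -0.113, -0.077 and 0.056 in replicates 1 to 4. The 10% of genes with the longest exons in sum had a median difference of 0.04 in replicate 1 and -0.04 in replicate 2, and the 10% with the shortest -0.07 and 0.04. These values were looked at after the calls were seen, they are across genes, which are not independent replicates, and no explanation was tested.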
